A study of Arabidopsis thaliana with 8 samples.

How the data were processed

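Poly(A) RNA was sequenced from rosette leaves 5 to 9 of 4 week old Arabidopsis thaliana plants of the Col-0 accession. Per the labels, plants grew in soil at 22 °C with 16 hours of light and 8 hours of dark, leaves were taken 4 hours after first light and frozen in liquid nitrogen, and strand-specific TruSeq mRNA libraries were made. The 8 libraries form 2 groups of 4, wild type (WT) and ABI3:MTA (mta), assigned from the sample titles. The labels do not say whether the libraries of a group came from separate plants, so p-values measure only the spread between these libraries, which may be partly technical. The miCLIP libraries that the series' design text mentions were not analysed here.

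Per the submitters' processing notes, the tools used before deposit included STAR 2.4.0, HTSeq and DESeq2, and the genome build was TAIR10. The notes as used here give no order or settings. The unit of the deposited values is a normalised signal per gene: read counts that the authors had divided by 1 factor per library, without rows below 1. This was tested on the values. In every library 100% of the listed values were whole multiples of a single step, within 0.02 of a step plus rounding, and the lowest listed value was 3 or 4 steps. A lowest value of 3 or 4 steps is what leaving out rows below 1 would give, since 1 unit was 2.73 to 3.98 steps. The lowest values therefore do not speak against 1 step being 1 read. The steps were nevertheless not treated as recovered reads in the tests between genotypes. The chi-square between pairs of libraries takes 1 step as 1 read. If 1 step is 1 read, the libraries hold 17132897 to 25377345 reads in genes. Rows for reads without a feature (4.92 to 5.97% of a library's deposited total), ambiguous reads (0.359 to 0.406%) and reads with more than 1 alignment (6.06 to 9.07%) stayed out of library sizes and tests.

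A count model had been planned before the data were examined; as the values are normalised, tests were run on a log scale instead. Genes absent from a library's list were set to 0, and genes with a deposited value of at least 3 in at least 4 libraries were kept (18328 of 20690). The deposited values were rescaled by trimmed mean of M values factors (30% of M and 5% of A values trimmed, as 0.3 and 0.05), which ranged from 0.883 to 1.08. The result is called the normalised read count below. log2(value + 1) was fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend and genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Every log2 fold change is mta minus WT on the log2(value + 1) scale, which understates the change of genes with low values. Gene lists were compared with all other tested genes by limma's camera with a preset correlation of 0.01, for lists with at least 5 tested genes, and again with an estimated correlation. limma's fry, planned beside it, tested whether a list's members moved together, without comparing them with other genes. Measures of whole libraries were compared by a two-sided exact permutation test over 70 assignments, whose smallest possible p is 0.02857.

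The groups, the 27 gene lists (473 genes), the alternatives and the rule for named genes were set before the data were examined. By that rule the text names MTA and ABI3; the 10 highest and 10 lowest log2 fold changes among genes past the threshold with a mean of at least 5 CPM and groups that do not overlap; up to 4 members of each list with the smallest adjusted p, or 1 where none passed; and the 2 most abundant genes past the threshold in each direction. Other genes are said to be named after their values were seen.

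Gene symbols, transcript lengths and descriptions came from the NCBI annotation of TAIR10.1, which matched 20582 of the 20690 gene identifiers. Because that build is not the one in the notes, no coordinates are given. Genes with near-identical copies, such as the Rubisco small subunit genes, are uncertain individually, since reads with several alignments were counted apart.

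The fit was tested on simulated tables of the mta against WT comparison over 18300 genes. It recovered 47 of 66 genes changed 1.5-fold (71.2%), 65 of 67 changed 2-fold (97.0%) and 66 of 66 changed 4-fold (100%), 3.26% of its calls were false, and it made 0 calls with no change planted. In these runs genes varied independently with a common dispersion, and libraries had no shared trend along transcript length. The share of false calls therefore need not hold for the real libraries. Alternatives covered other scalings, filters, pseudocounts, precision weights, removal of organelle genes, a replicate block, the removal of each library and, chosen after seeing the data, the authors' scaling, a correction for transcript length and the removal or merging of libraries that stood apart or lay close together. Figures were drawn with matplotlib 3.10.9.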

Results

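Messenger RNA was compared between leaves of wild-type Arabidopsis and of ABI3:MTA plants (mta). MTA is the catalytic subunit of the methyltransferase that writes N6-methyladenosine (m6A) into mRNA. In ABI3:MTA plants a loss-of-function mutant is carried through embryo development by MTA expressed from the embryo-active ABI3 promoter. The comparison asks which leaf transcripts differ in abundance between plants with the normal MTA gene and these plants. There were 4 libraries per genotype. If a step of the deposited values is 1 read, they hold 17132897 to 25377345 reads in genes. They list 19204 to 19716 genes each, and 18411 genes are listed in all 8. Group values below are normalised read counts as mean ± SD with n = 4 libraries per genotype.

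The first principal component separated the genotypes and held 51.7% of the variance. The second held 26.2% and spread the libraries within both genotypes, with WT 1 and mta 1 at one end and mta 4 at the other. Its gene loadings ran with transcript length (Spearman's rho = -0.56 across genes, which are not independent replicates). WT 2 and WT 3 lay closest together, with a chi-square per degree of freedom, which takes 1 step as 1 read, of 1.76 against 5.42 to 63.7 for the other pairs within a genotype, and were kept as separate samples.

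**Figure D1:**
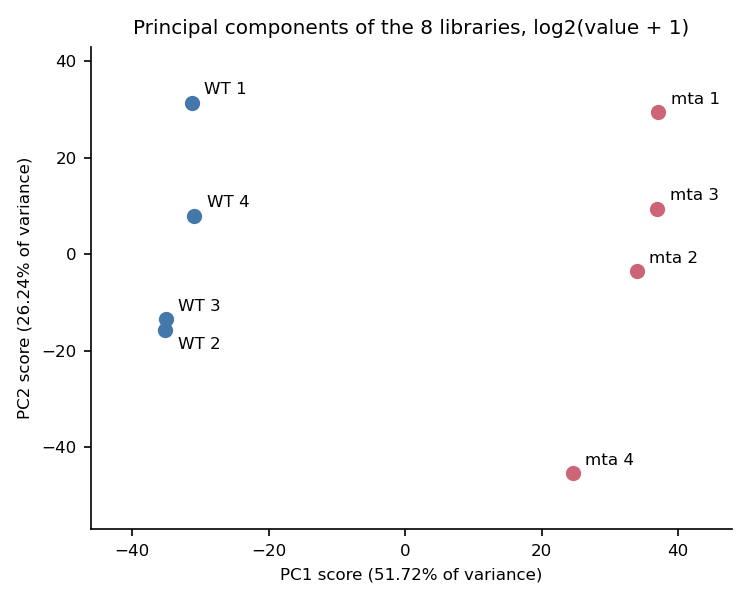
Scores of the 8 libraries on the first (x axis, 51.7% of variance) and second (y axis, 26.2%) principal components of log2(value + 1), with WT in blue and mta in red. The genotypes separate along the first component, and mta 4 lies apart along the second.

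MTA (AT4G10760) transcripts were lower in mta, at 51.0 ± 10.7 against 72.5 ± 8.32 in WT, a log2 fold change of -0.52 with a standard error of 0.15 (limma adjusted p = 0.0312). All 4 mta libraries lay below all 4 WT libraries. Values per gene do not part transcripts of the resident locus from those of the ABI3-driven copy. The call was lost without some single libraries. The limma adjusted p for MTA was 0.0944 without WT 2, 0.0653 without WT 3, 0.0629 without WT 4 and 0.0531 without mta 1, with log2 fold changes of -0.44, -0.53, -0.54 and -0.45. Without WT 3 or WT 4 the change was no smaller, so here and below a lost call can reflect fewer libraries alone. Over all genes, 3285 to 3515 were called without WT 2, WT 3, WT 4, mta 2 or mta 3, against 4842 with all libraries. With upper-quartile factors the limma adjusted p for MTA was 0.0532. Without WT 1, mta 1 and mta 4 its log2 fold change was -0.29 with an adjusted p of 0.0605. ABI3 (AT3G24650) was not listed in any library.

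Among changed genes with a mean of at least 5 CPM and genotypes that do not overlap, the highest log2 fold changes were those of AT3G01345 (8.55), AT5G35935 (3.96), ARD3 (3.90) and FMO1 (3.73), and the lowest those of SAG29 (-4.00) and SAG12 (-3.11). FMO1, which makes the systemic immune signal N-hydroxypipecolic acid, rose from 8.99 ± 0.840 to 132.0 ± 17.5, and UGT76B1, which glucosylates that signal and salicylic acid, rose from 20.3 ± 2.73 to 165.5 ± 12.2. SAG29, a sugar transporter gene linked to senescence, fell from 185.9 ± 19.3 to 11.0 ± 3.02, and SAG12, a cysteine protease gene used as a senescence marker, fell from 67.4 ± 7.29 to 7.23 ± 2.86. The limma log2 fold changes were 3.73 ± 0.13 (SE, adjusted p = 7.04e-08), 2.97 ± 0.12 (1.84e-07), -4.00 ± 0.18 (2.48e-07) and -3.11 ± 0.23 (7.33e-06).

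Over all genes, limma called 4842 of 18328 tested genes changed (26.4%), 2436 higher and 2406 lower in mta. Of these, 799 changed at least 2-fold, 576 of them higher and 223 lower. The genotypes did not overlap for 5199 genes (28.4%, against 2.86% by chance). The balance of directions depended on the scaling: with the authors' scaling alone, 1671 genes were higher and 4249 lower (71.8% lower, against 49.7%), and the median log2 fold change of all tested genes moved from -0.02 to -0.16. Without mta 2, the number of genes lower in mta was 1570, and without WT 1, mta 1 and mta 4 together 8485 genes were called changed. With WT 2 and WT 3, the closest pair, averaged as 1 sample, 3545 genes were called (1825 higher and 1720 lower). Of these, 3538 were also called with all libraries, in the same direction. Leaving out WT 2 or WT 3 gave 3515 and 3484 calls.

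SBT3.3, a subtilase linked to immune priming, rose from 45.7 ± 1.68 to 420.3 ± 37.7, and AT4G10500, a salicylic acid hydroxylase, rose from 73.2 ± 10.3 to 530.4 ± 55.0. AT3G13610, the feruloyl-CoA hydroxylase of scopoletin synthesis, rose from 9.84 ± 2.70 to 83.6 ± 12.5. ARD3, an acireductone dioxygenase, rose from 15.6 ± 3.93 to 242.5 ± 27.5, EDA36 from 6.56 ± 0.978 to 73.2 ± 6.87, AT1G59930, a MADS-box family gene, from 14.9 ± 2.37 to 113.8 ± 31.4, and AT5G35935, which is uncharacterised, from 9.29 ± 1.16 to 160.0 ± 23.9. The uncharacterised gene AT3G01345 was listed in 1 of 4 WT libraries, at a deposited value of 1.47, and in all 4 mta libraries at 342.1 to 520.7. With the unlisted libraries set to 1, the highest value they can have, its mean was at least 400 times higher in mta.

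Among the genes with the lowest fold changes, CCD8, a carotenoid cleavage enzyme of strigolactone synthesis, fell from 72.4 ± 7.46 to 16.9 ± 2.75. CYP707A3, which inactivates abscisic acid, fell from 624.4 ± 107.1 to 179.4 ± 19.7. LEA4-5, a late embryogenesis abundant protein gene, fell from 53.7 ± 14.0 to 13.9 ± 2.57. FBS1, an F-box gene induced by stress, fell from 263.6 ± 13.0 to 71.8 ± 7.72, and AT5G51190, an ERF-type transcription factor gene, from 530.8 ± 34.0 to 153.5 ± 27.4. PP2-B13, a phloem protein gene, fell from 127.5 ± 13.1 to 32.4 ± 4.05, and AT5G05250, uncharacterised, from 130.9 ± 13.0 to 34.4 ± 2.94. The most abundant genes past the threshold were RBCS1A (134812 ± 10240 in WT and 251944 ± 63868 in mta) and DRT112, a plastocyanin gene (32064 ± 3616 and 50405 ± 9217), among those higher. Among those lower they were PEN3, a defence transporter gene (13365 ± 2163 and 9308 ± 1173), and J8, a chaperone gene (11588 ± 522 and 8703 ± 519). Leaving out single libraries ended the call for DRT112 (limma adjusted p of 0.0534 without WT 2, 0.0552 without WT 3 and 0.0545 without mta 3). It ended the call for PEN3 as well (0.0743 without WT 2, 0.0761 without WT 3, 0.0622 without WT 4, 0.0692 without mta 2 and 0.0730 without mta 3).

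**Figure D2:**
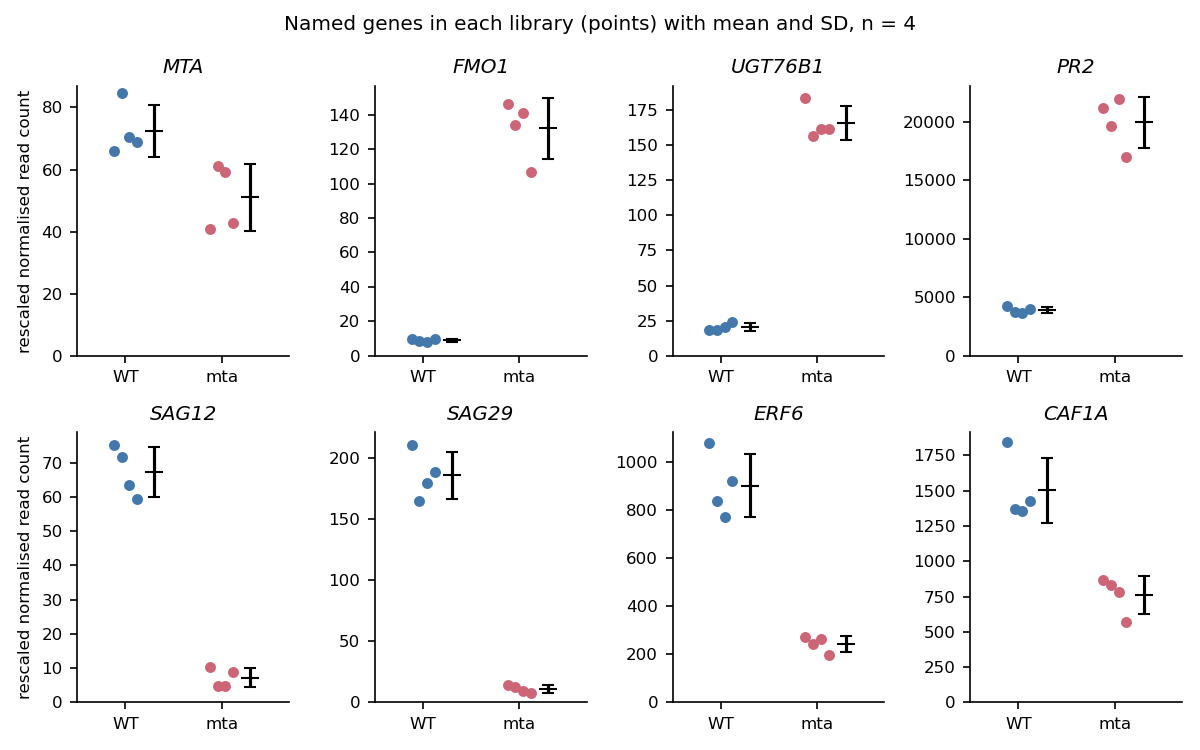
Normalised read counts (y axis, from 0) of 8 named genes in the 4 WT (blue) and 4 mta (red) libraries, with the mean and SD beside the points. For each of these genes the libraries of the genotypes do not overlap.

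The means of markers of other leaf cell types differed between the genotypes beside the gene lists that follow, but neither marker list passed camera after adjustment. The mean of the epidermis and guard cell markers was higher in mta by 0.40 and that of the vasculature markers by 0.25 on the log2 scale, with no overlap of the genotypes (two-sided exact permutation p = 0.02857, the smallest possible, adjusted p = 0.0657 over 23 lists). The genotypes did not overlap either in the means of the salicylic acid, wound and touch, glucosinolate, salt and drought, auxin and phosphate lists, at the same p. Every list at this smallest possible p had an adjusted p of 0.0657. No list therefore passed the permutation test after adjustment, and that outcome does not part the marker lists from the others.

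Of 26 genes of the salicylic acid and immune response, 15 rose, 1 fell and 10 did not pass (15 and 3 passed, higher and lower, when adjusted over the list alone). PR2, a beta-glucanase and marker of the response, rose from 3923 ± 269 to 19949 ± 2180, and PR5, a thaumatin-like marker, from 2061 ± 331 to 11908 ± 1908. PAD3, the last enzyme of camalexin synthesis, rose from 155.0 ± 6.51 to 619.1 ± 70.3. The member that fell, named after its value was seen, was CBP60G, a transcription factor gene of salicylic acid synthesis (log2 fold change -0.47). Without WT 1, 3 members fell, and 2 fell without mta 1 or without mta 4, while 3 fell with the authors' scaling. The list's median log2 fold change was 0.59, with a camera adjusted p of 3.01e-07 at the preset correlation and an adjusted p of 0.179 with an estimated correlation.

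The rapid wound and touch response list went the other way, with 12 of 16 members lower, 0 higher and 4 not past the threshold (12 lower when adjusted over the list alone). ERF6 fell from 902.7 ± 132.1 to 244.6 ± 33.6, ERF5 from 429.4 ± 51.3 to 160.3 ± 23.8 and ERF104 from 779.4 ± 32.6 to 315.8 ± 50.9, all genes of ethylene response factors. SZF1, a zinc finger gene, fell from 2318 ± 300 to 1083 ± 70.3. The median log2 fold change was -0.76 (camera adjusted p = 1.37e-07, and adjusted p = 0.263 with an estimated correlation).

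Genes of glucosinolate synthesis and breakdown were mostly higher, with 16 of 24 members higher, 1 lower and 7 not past the threshold (17 and 1 when adjusted over the list alone). MAM3, of methionine chain elongation, rose from 157.7 ± 11.5 to 324.5 ± 33.3, SUR1, a C-S lyase, from 837.3 ± 36.2 to 1456 ± 64.4, and CYP79B2, of indole glucosinolate and camalexin synthesis, from 324.2 ± 13.5 to 578.0 ± 51.3. MYB51, a regulator of the indole branch, fell from 559.0 ± 46.3 to 302.0 ± 20.4. The median was 0.61 (camera adjusted p = 1.12e-06, and adjusted p = 0.157 with an estimated correlation). With the authors' scaling 13 were higher and 2 lower.

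Among 36 nuclear photosynthesis genes, 8 were higher, 0 were lower and 28 did not pass (6 higher when adjusted over the list alone). RBCS1B (1012 ± 91.6 and 1996 ± 452 in WT and mta), RBCS2B (15009 ± 1103 and 28511 ± 5657) and RBCS3B (17553 ± 2225 and 31465 ± 7038), all Rubisco small subunit genes, rose, but they are near-identical copies and uncertain individually. PSAD2, of photosystem I, rose from 13269 ± 794 to 20165 ± 2196. The median was 0.33 (camera adjusted p = 0.000118, and adjusted p = 0.682 with an estimated correlation). By fry the list did not pass (adjusted p = 0.111). The number of members higher in mta varied with the libraries used. It was larger, at 15, without WT 1 or without mta 4, and 31 without WT 1, mta 1 and mta 4 together. It was 6 without WT 2, WT 3, WT 4, mta 1, mta 2 or mta 3. The median fell to 0.19 without mta 1 and to 0.18 with the authors' scaling.

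In the salt, drought and abscisic acid response list, 13 of 33 members fell, 3 rose and 17 did not pass (14 and 3 when adjusted over the list alone). NCED3, the stress-induced enzyme of abscisic acid synthesis, fell from 244.6 ± 5.17 to 130.8 ± 23.7. The dehydrin genes LTI30 (313.0 ± 11.0 to 180.0 ± 3.59) and ERD10 (5568 ± 227 to 3798 ± 123) fell, as did AZF2, a zinc finger repressor gene (409.7 ± 12.5 to 264.3 ± 26.0). The 3 members that rose, named after their values were seen, were RD29B (1.42), HKT1 (1.01) and COR15A (0.66 on the log2 scale). The median was -0.25 (camera adjusted p = 0.0115, and adjusted p = 0.469 with an estimated correlation). The list's camera adjusted p was 0.0840 without WT 1, with a median of -0.32, and 0.0756 without WT 1, mta 1 and mta 4, with a median of -0.20. With the authors' scaling the median was -0.40. Members that rose numbered 5 without WT 1, 5 without mta 4 and 6 without the 3 libraries, while leaving out WT 2, WT 3, WT 4 or mta 1 ended the call for HKT1 (limma adjusted p of 0.0591 to 0.0679).

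Of 15 auxin response and transport genes 7 fell, 0 rose and 8 did not pass (8 lower when adjusted over the list alone). The repressor genes IAA1 (100.6 ± 15.9 to 51.9 ± 2.37), IAA3 (229.5 ± 14.6 to 147.0 ± 14.0), IAA17 (122.0 ± 27.4 to 72.0 ± 12.2) and IAA29 (114.4 ± 8.71 to 75.5 ± 3.64) were among them. The median was -0.28 (camera adjusted p = 0.00467, and adjusted p = 0.179 with an estimated correlation). The number of auxin genes that fell was 4 without WT 4, mta 2 or mta 3, and 10 with the authors' scaling. Of 6 tested phosphate starvation genes 4 rose, 1 fell and 1 did not pass, with the same counts when adjusted over the list alone. PAP17, a purple acid phosphatase gene, rose from 79.7 ± 4.18 to 167.9 ± 27.9, PHT1;4, a phosphate transporter gene, from 28.0 ± 1.60 to 45.7 ± 3.03, PS2, a phosphatase gene, from 12.7 ± 0.681 to 25.9 ± 4.90, and SRG3 from 39.8 ± 1.74 to 62.9 ± 9.56. The member that fell, named after its value was seen, was SQD2 (-0.30), whose call was lost without WT 2, WT 3, WT 4, mta 2 or mta 3 (limma adjusted p of 0.0554 to 0.0806). The phosphate list's median was 0.66 (camera adjusted p = 0.0186, and adjusted p = 0.179 with an estimated correlation). Without the filter on low values its camera adjusted p was 0.0848, with a median of 0.52 and 4 higher and 1 lower of 8 tested.

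**Figure D3:**
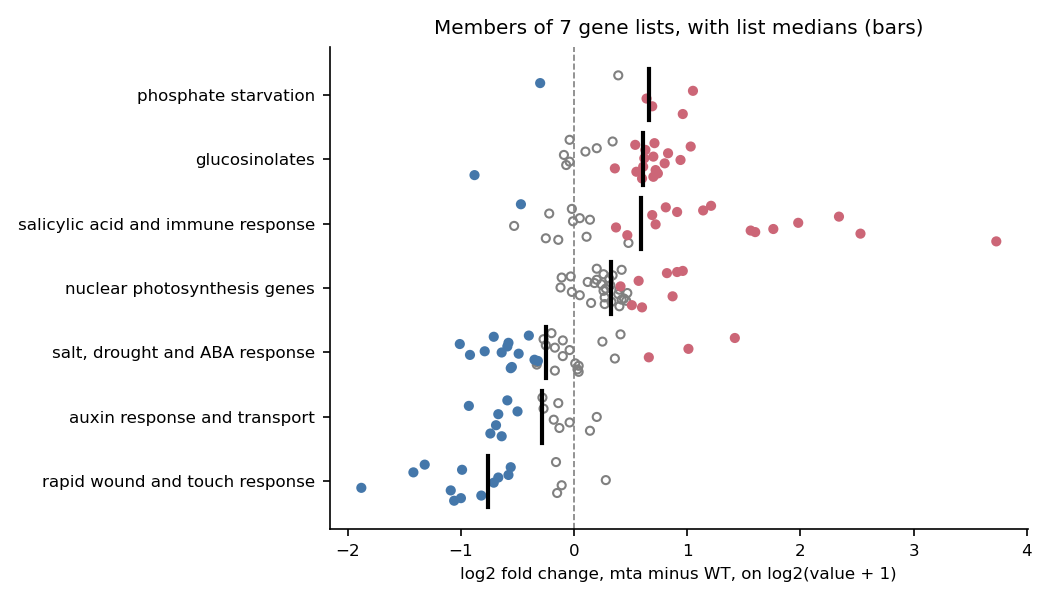
Log2 fold changes (x axis, mta minus WT on log2(value + 1)) of the members of the 7 gene lists past the camera threshold, with each list's median as a black bar. Filled points passed the limma threshold (red higher, blue lower in mta) and open points did not; 12 of the 16 wound and touch genes lie below 0 and passed.

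None of the other 16 lists tested by camera passed at the preset correlation. Among the 8 m6A writers, FIP37, a subunit of the writer complex, rose from 62.7 ± 8.70 to 96.7 ± 14.0 (limma adjusted p = 0.00934, but 0.0514 with the authors' scaling), MTA fell and 6 did not pass. Without mta 1, 2 writers were higher, and leaving out WT 2, WT 3, WT 4 or mta 1 ended the call for MTA as given above. Of 15 m6A readers and erasers tested, 5 rose and 2 fell, but 1 fell without WT 2, WT 3, WT 4, mta 2 or mta 3. The reader genes ECT3 (202.2 ± 10.8 to 307.7 ± 5.69), ECT2 (1922 ± 113 to 2752 ± 219) and CPSF30 (68.0 ± 4.84 to 102.0 ± 8.21) rose, and ECT1 fell from 172.1 ± 8.04 to 125.5 ± 15.2. The list's median of 0.08 had the opposite sign under the authors' scaling (-0.06), where 3 rose and 3 fell. It also depended on single libraries, at 0.03 without WT 1, 0.17 without WT 2, 0.04 without WT 4, 0.14 without mta 1, 0.13 without mta 3 and 0.02 without mta 4. The camera adjusted p was 0.529 for writers and 0.282 for readers and erasers. Adjusted over the list alone, 2 writers were higher and 1 lower, and 6 readers or erasers were higher and 2 lower.

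Of 24 mRNA decay genes 1 passed with all libraries, CAF1A, a deadenylase gene, which fell from 1502 ± 233 to 762.9 ± 133.5 (1 lower also when adjusted over the list alone, camera adjusted p = 0.347). This count was larger in some settings, with 3 members lower without WT 1, 2 without mta 1, 4 without mta 4, 9 without those 3 libraries together and 5 with the authors' scaling. It stayed at 1 without WT 2, WT 3, WT 4, mta 2 or mta 3. In the small RNA pathway 4 of 15 genes fell and 0 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.262). SGS3 fell from 87.3 ± 11.3 to 44.3 ± 13.4. DCL4 (55.7 ± 11.4 to 35.3 ± 11.6), RDR6 (83.2 ± 16.3 to 56.4 ± 13.1) and AGO2 (92.8 ± 8.43 to 70.9 ± 10.5), which act with SGS3 in making or using small RNAs, passed with all libraries. Leaving out WT 2, WT 3, WT 4, mta 1, mta 2 or mta 3 ended each of those 3 calls, with limma adjusted p-values of 0.0679 to 0.113 for DCL4, 0.0820 to 0.120 for RDR6 and 0.0766 to 0.119 for AGO2, while 7 genes fell without WT 1, mta 1 and mta 4, and 2 with upper-quartile factors.

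The jasmonate response list was split, with 4 of 22 tested genes higher and 5 lower (6 and 7 when adjusted over the list alone, camera adjusted p = 0.991). TAT3, a tyrosine aminotransferase gene, rose from 887.1 ± 44.2 to 4509 ± 549 and LOX2, of jasmonate synthesis, from 10392 ± 929 to 22484 ± 986. The lipoxygenase gene LOX4 fell from 1734 ± 145 to 722.4 ± 58.0 and VSP2, a storage protein gene, from 1842 ± 153 to 930.9 ± 130. Leaving out mta 4 gave 8 jasmonate genes higher and 5 lower, leaving out WT 1 gave 4 and 8, and leaving out WT 3, WT 4 or mta 2 gave 4 and 3. With upper-quartile factors 6 were higher and 3 lower. Leaf senescence genes also went both ways, 3 higher and 3 lower of 13 (3 and 4 when adjusted over the list alone, camera adjusted p = 0.377). By fry the senescence list was lower in mta (adjusted p = 0.000573), with a mean log2 fold change of -0.50 and a median of -0.02. Beside SAG12 and SAG29, SEN1 fell from 1091 ± 57.4 to 623.9 ± 28.2, and SAG13 rose from 1361 ± 75.3 to 2887 ± 518. Of the senescence genes 1 was higher without WT 4, without mta 2 and with the authors' scaling. Of 24 expansin and xyloglucan endotransglucosylase genes, which act on the cell wall, 6 rose and 5 fell (7 and 5 over the list alone, camera adjusted p = 0.347), among them XTH16 (28.6 ± 2.99 to 69.1 ± 9.39) and XTH9 (55.0 ± 6.08 to 96.2 ± 10.6), which rose, and XTH18 (395.2 ± 10.5 to 187.8 ± 13.6) and EXPA8 (626.2 ± 89.7 to 295.7 ± 59.5), which fell. In this list 13 genes were higher and 5 lower without mta 4, as without WT 1, mta 1 and mta 4, and 3 were lower without WT 2, WT 3 or WT 4.

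Of 21 circadian clock genes 2 rose and 4 fell, with the same counts over the list alone (camera adjusted p = 0.262). GI fell from 497.2 ± 61.5 to 289.1 ± 22.1 and LHY rose from 133.9 ± 4.60 to 175.5 ± 14.0. RVE8 (55.9 ± 4.93 and 79.2 ± 13.2) and CDF1 (77.4 ± 10.8 and 55.1 ± 9.11) passed with all libraries, but limma adjusted p-values reached 0.0661 for RVE8 (lost without WT 1, WT 2 or mta 3) and 0.0917 for CDF1 (lost without WT 2, WT 3, mta 1, mta 2 or mta 3). Clock genes lower in mta numbered 7 without WT 1 or mta 4, and 1 without WT 2, WT 3, mta 1, mta 2 or mta 3. Those higher numbered 1 without WT 2 or mta 3 and 1 with the authors' scaling. Among 15 tested flowering time genes 3 rose and 2 fell (3 and 4 over the list alone, camera adjusted p = 0.827). MAF5 rose from 30.3 ± 1.82 to 61.1 ± 3.80 and SPL3 from 36.0 ± 6.09 to 64.2 ± 3.51, while SOC1 fell from 547.5 ± 23.4 to 402.4 ± 59.1. FUL (11.7 ± 1.18 and 19.4 ± 4.03) passed with all libraries, but was lost without WT 3, mta 1, mta 2 or mta 3 (limma adjusted p of 0.0541 to 0.0698). Without WT 2, WT 4, mta 1, mta 2 or mta 3, 1 flowering time gene fell, as with upper-quartile factors, while 4 fell with the authors' scaling. Without WT 1, mta 1 and mta 4 together, 6 rose and 1 fell. Of 15 tested flavonoid and anthocyanin genes 3 rose and 0 fell, with the same counts over the list alone (camera adjusted p = 0.262), including CHS, the entry enzyme of the pathway (320.9 ± 53.2 to 576.3 ± 104), and its regulators PAP1 (46.0 ± 5.75 to 80.1 ± 12.8) and PAP2 (0.741 ± 0.873 to 4.17 ± 0.968), and 1 fell without WT 1. Of 13 tested heat shock genes HSP18.2 rose from 15.4 ± 5.46 to 96.8 ± 5.93 and 11 did not pass (1 higher and 0 lower over the list alone, camera adjusted p = 0.262). BAG6 was lower with all libraries (72.2 ± 10.4 and 47.6 ± 16.1), but its limma adjusted p was 0.0732 to 0.116 without any 1 of WT 2, WT 3, WT 4, mta 1, mta 2 or mta 3, and 2 heat shock genes fell without mta 4.

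Of 23 cytosolic ribosomal protein genes 2 rose and 3 fell, and 0 passed when adjusted over the list alone (camera adjusted p = 0.991). The balance depended on the scaling, with 1 higher and 7 lower under the authors' scaling, and 2 higher and 0 lower with upper-quartile factors. Without WT 1, mta 1 and mta 4, 7 were higher and 5 lower. Those that passed with all libraries were RPS6A (0.46), RPL23AA (0.30), RPS18C (-0.41) and RPS13A (-0.41 on the log2 scale) and, named after its value was seen, RPL5A (-0.32). These 5 calls were lost in fits with 1 library fewer: limma adjusted p-values reached 0.0553 for RPS6A (lost without WT 2, WT 3 or WT 4), 0.0929 for RPL23AA (lost without any library but WT 1 and mta 4), 0.118 for RPS18C (lost without WT 3, WT 4, mta 2, mta 3 or mta 4), 0.133 for RPS13A (lost without any library but mta 1) and 0.144 for RPL5A (lost without any library but mta 4). In the cell cycle list 0 of 18 tested genes passed the limma threshold (PCNA2 at 33.8 ± 6.65 and 23.0 ± 7.37 had the smallest p, camera adjusted p = 0.557 for the list), 3 had an unadjusted p under 0.05 and voom called 0, but without mta 4 PCNA2 passed (limma adjusted p = 0.00986), and 1 member was lower with the authors' scaling. The trichome list also had 0 of 10 by limma and by voom, and 0 with an unadjusted p under 0.05 (TTG2 at 9.68 ± 2.2 and 7.18 ± 1.85, camera adjusted p = 0.991), but 1 fell without WT 1, 1 rose without mta 4, and 1 fell with the authors' scaling.

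Of 9 tested epidermis and guard cell markers 3 rose and 0 fell (4 and 0 over the list alone, camera adjusted p = 0.108), led by PDF1 (12.7 ± 5.46 to 28.9 ± 2.68), with FAMA (104.2 ± 11.4 to 145.2 ± 17.2; limma adjusted p = 0.119 with the authors' scaling) and MYB60 (85.5 ± 13.1 and 123.9 ± 26.8). Their median log2 fold change of 0.43 rested on single libraries, at 0.21 without WT 1, 0.18 without mta 4 and 0.04 without WT 1, mta 1 and mta 4. Of 10 vasculature markers 3 rose and 0 fell, with the same counts over the list alone (camera adjusted p = 0.0926), led by PP2-A1 (1481 ± 157 to 2239 ± 130), with XCP2 (log2 fold change 0.54 ± 0.13, SE) and SUC2 (894.8 ± 46.5 and 1132 ± 125). Their median was 0.28, but 0.18 without mta 4 and 0.14 with the authors' scaling. Single libraries ended the calls for MYB60 (without any but WT 2 and mta 1, limma adjusted p of 0.0577 to 0.134) and SUC2 (without any but WT 1 and mta 4, 0.0550 to 0.0889). With the authors' scaling 1 epidermis marker was higher and 1 lower. Too few members were tested for camera in the remaining lists: of 4 iron deficiency genes FER1, a ferritin gene, rose from 952.5 ± 95.7 to 1917 ± 250 and NAS4 was at 48.8 ± 5.79 and 35.6 ± 2.89, with 2 higher without mta 4, the root marker PYK10 fell from 131.0 ± 4.67 to 69.8 ± 19.7, the flower gene AG was at 2.55 ± 0.336 and 5.18 ± 1.45, and of 2 seed maturation genes tested neither passed (OLEO4 at 4.32 ± 2.02 and 1.96 ± 1.51). NAS4 and AG passed with all libraries, but limma adjusted p-values reached 0.0732 for NAS4 (lost without WT 3, WT 4, mta 2 or mta 3) and 0.106 for AG (lost without any library but mta 2). Without the filter on low values, 1 of 5 seed maturation genes tested was lower, and of 7 iron deficiency genes 1 was higher and 2 lower. Named after their values were seen, EM6 and BHLH101 were listed in all 4 WT libraries and 0 mta libraries. Their WT means, 2.074 and 2.095 in the deposited unit, lie near the lowest listed values.

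The share of reads with more than 1 alignment was 6.49 ± 0.423% in WT and 8.41 ± 0.493% in mta, and the share of ambiguous reads 0.402 ± 0.00289% and 0.369 ± 0.0117%. The genotypes did not overlap in either (two-sided exact permutation p = 0.02857, the smallest possible, adjusted p = 0.114 over 8 library measures). The 10 most abundant genes took 10.8 ± 1.17% of the signal in WT and 13.0 ± 1.37% in mta (exact permutation p = 0.0571, adjusted p = 0.152). The slope of a library's deviations on log2 transcript length was 0.0386 ± 0.159 in WT and -0.0386 ± 0.180 in mta (exact permutation p = 0.571, adjusted p = 0.653).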

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

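The test of the second axis was set before its result was seen, but the choice between its 2 measures, share and variance, was settled after both were seen. By variance alone the bound set for length as the main source would have been passed, although 64.5% of the variance was left. Of 218 groups of 4 libraries examined, for 8 library measures and 101 named genes, 13 held a library far from the other 3; chance alone would give about 10.9. WT 1 was the library apart in 6 of them and mta 4 in 5. WT 1 was above the other WT libraries for CPSF30 (75.2), CAF1A (1849), SZF1 (2762), HSP18.2 (23.5), RPS6A (716.4) and PP2-A1 (1715). mta 4 was below the other mta libraries for ARD3 (201.5), AT5G51190 (112.4) and FUL (13.4), and above them for TTG2 (9.93) and PEN3 (11048). mta 1 was above the others for EDA36 (83.4), and AT3G01345 was listed in WT 2 alone among the WT libraries (1.36).

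WT 1, mta 1 and mta 4 also stand at the ends of the second principal component, whose loadings ran with transcript length. A length-dependent difference between libraries, such as in RNA integrity, is a candidate explanation. With each library's trend along transcript length removed, the components were computed anew. The second component's share of the variance outside the first went from 54.4 to 44.0%, which leaves 81.0% of that share. Its variance was 64.5% of that of the original second component. The share left lies between what length as the main source and length as no source would give, so the contribution cannot be told apart from a difference between the plants of each library. A biological source within a genotype was not tested, as the labels name none.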

How the results depend on the processing

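The settings that use the authors' scaling, pseudocounts of 0.5 and 5, unlisted genes set to 1, removal of the length trend, WT 2 and WT 3 averaged, or WT 1, mta 1 and mta 4 left out were chosen after seeing the data; the others were planned. The planned DESeq2 alternative was not run, since the values are normalised. Genes changed between mta and WT numbered 3285 to 6627 without single libraries and 8485 without WT 1, mta 1 and mta 4; 4649 of the 4842 calls were among them, in the same direction. Genes higher in mta numbered 1715 to 3224 without single libraries and 4031 without the 3 libraries. Genes lower in mta numbered 1570 to 3403 without single libraries, 3988 with library size only, 4249 with the authors' scaling and 4454 without the 3 libraries. Genes changed at least 2-fold numbered 769 to 886 without single libraries and 492 with a pseudocount of 5. MTA was between -0.61 and -0.44 on the log2 scale without single libraries, with limma adjusted p-values of 0.0274 to 0.0944; it lost its call at -0.45 with upper-quartile factors, -0.49 with WT 2 and WT 3 as 1 sample and -0.29 without the 3 libraries, and the cause was not tested. The number of gene lists past the threshold was 6 to 9 without single libraries and 0 with an estimated correlation. By fry the photosynthesis list did not pass (adjusted p = 0.111) and the leaf senescence list passed as lower (adjusted p = 0.000573). The senescence list had a mean log2 fold change of -0.50 but a median of -0.02, with SAG29 at -4.00 and SAG12 at -3.11. The other lists kept their camera call by fry. Of 98 named genes past the threshold 80 passed without each library in turn and 77 in all 23 settings, and 0 of the 101 tested reversed. Within single lists, the number of called genes moved by over 1.5 times without single libraries for most lists, which is given beside each. For the camera test of single lists, 498 values over 22 settings kept their call, 3 lost it, 5 gained it and 0 reversed. Of the library measures 61 values kept their side of 0.05 and 4 lost it, all of them the ambiguous share without a WT library. Libraries with the same replicate number did not all deviate together (r = 0.47, 0.08, -0.20 and -0.35), although WT 1 with mta 1 had the highest r of all WT and mta pairs. These values do not settle whether the numbers pair the samples. With the replicate block 4516 genes were called, and WT and mta libraries did not all correlate best with their own number. Genes below 1 in the deposited unit are beyond the reach of these tables.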

Other observations

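The tests of families formed from words in the gene descriptions, of list means per library, of the libraries that stood apart, of time of day and of handling were chosen after the result was seen, and the error allowed for in the tests of abundant genes and of loci around MTA was added after. Of 38 glutathione S-transferase genes, which act in detoxification, 19 were higher in mta and 1 lower (median log2 fold change 0.56, camera adjusted p = 1.39e-08, and adjusted p = 0.244 with an estimated correlation). Of 94 UDP-glycosyltransferase genes 31 were higher and 7 lower (0.20, camera adjusted p = 0.000451, and adjusted p = 0.738 with an estimated correlation), and of 16 chitinase genes 9 were higher and 0 lower (0.51, camera adjusted p = 0.000174, and adjusted p = 0.557 with an estimated correlation). Protein phosphatase 2C genes went the other way, 3 higher and 16 lower of 54 (-0.21, camera adjusted p = 0.00415, and adjusted p = 0.244 with an estimated correlation), as did NLR disease resistance genes, 5 higher and 16 lower of 110 (-0.30, camera adjusted p = 0.00097, and adjusted p = 0.857 with an estimated correlation). In all, 9 of 29 families passed at the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.244. As 19 of the 35 splits of the libraries gave 9 or more families, and 1 of the others 16, chance is not excluded for that number. Splits with 3 libraries of a genotype on one side carry part of the genotype difference, so this count does not measure chance alone.

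Of genes listed in all 4 libraries of one genotype and at most 1 of the other, 103 were in mta and 61 in WT, a ratio of 1.69, between what a one-sided gain and an even exchange would give. With a mean of at least 10 in the deposited unit there were 6 and 2. Named after their values were seen, MRD1 was at least 35.2-fold higher in mta, and GPAT5, of suberin synthesis, and LEA7 at least 14.3-fold and 12.3-fold lower, with unlisted libraries set to 1. Of 89 tested loci among the 100 on each side of MTA, 31 had changed (34.8%, exact binomial interval 25.0 to 45.7%, against 26.4% of all others, Fisher's exact p = 0.0905), so a segment linked to the MTA mutation is neither shown nor excluded.

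The real split of the libraries was the only 1 of 35 with as many changed genes (4842, highest other 1126). The same held for genes changed at least 2-fold (799, highest other 98) and for genes in one direction (2436 higher and 2406 lower, highest other 884). Being 1 of 35 is the smallest share this test can give, and every other split mixes the genotypes, so it does not by itself exclude chance. The other split with 1126 genes set WT 1, mta 1, mta 2 and mta 3 against the rest, so it held 3 of the 4 mta libraries on one side. For gene lists, 14 of the 35 splits gave 7 or more past the threshold, and 1 of the others 10, so chance is not excluded for that number. Each of the others with 7 or more held 3 libraries of a genotype on one side, and so carried part of the genotype difference. The count of 14 splits therefore does not measure chance alone. Splits with 2 libraries of each genotype on a side do not set one genotype against the other, and they called 0 genes changed. They still gave 0 to 6 lists, against 7 for the real split. Camera at the preset correlation can thus pass up to 6 lists from differences between libraries within the genotypes. For the mean of each list in each library, the genotypes did not overlap for 10 of 23 lists, among them 6 of the 7 past the camera threshold, all but photosynthesis, and the heat shock, leaf senescence, epidermis and vasculature lists (two-sided exact permutation p = 0.02857, the smallest possible, adjusted p = 0.0657). For leaf senescence the difference in means was -0.50, while the members' median log2 fold change was -0.02.

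The salicylic acid list was higher and the wound and touch list lower in mta. Length-dependent library differences are argued against as the whole cause, since with the length trend removed the medians were 0.56 and -0.77, and so are the 3 libraries that stood apart, without which they were 0.74 and -0.71. A shift in time of day could move wound and touch genes, but the labels give harvest at 4 hours after first light for every library. In the values, 7 morning clock genes less 8 evening clock genes gave a median difference of -0.11 (exact permutation p = 0.479). That does not decide whether a shift within the labelled time remained. Handling at harvest cannot be told apart from genotype, as 13 of the 16 wound and touch genes had all mta libraries below all WT libraries and the labels name no harvest batch. Reduced m6A writing stays open as a biological explanation, untested beyond the genotype contrast, as does a change in the makeup of cell types. The means of the epidermis and vasculature markers did not overlap between the genotypes, but neither list passed camera (adjusted p = 0.108 and 0.0926). The epidermis median also rested on single libraries, as given above.

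Under total scaling more genes were lower than higher in mta (69.7% of 5720 calls). A few abundant genes taking more reads in mta could give this, and leaving the 10 most abundant genes out of the totals moved the median log2 fold change of all genes from -0.14 to -0.11, with a standard error between libraries of 0.05. That does not decide between a few abundant genes and a broader shift, since the bound set against the first, below -0.1, was passed by less than the error.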
